A study of Mus musculus with 8 samples.

How the data were processed

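The 8 libraries were of lymph node CD8 T cells positive for Ly6C and CXCR3, from B6 and CD103Tg mice, 4 per group. Per the labels' protocols, RNA was extracted with a column kit and checked on a Tapestation, and libraries were made with SMART-Seq v4, which amplifies cDNA from very small RNA amounts without molecular identifiers, and Nextera XT. Such libraries do not mark the strand, so reads from overlapping genes cannot be told apart by strand. The submitters' processing notes name bcl2fastq 2.17, cutadapt 1.18, STAR 2.7.0f and RSEM, with the builds GRCm38 and mm10. The annotation is not given in the sources used here, but all 13245 gene IDs, with their versions, matched GENCODE M21, whose GRCm38 coordinates are given.

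The authors deposited 1 table for all libraries, which per the labels holds TMM-scaled CPM values of a filtered gene set. The rule of that filter is not given in the sources used here. The deposited values are a normalized gene-level signal, CPM on a TMM-scaled library size, and not counts. The columns sum to 962335 to 1022065, since TMM factors move the sum. All values were whole multiples of 0.01 of a read within 0.05 of a hundredth, and 63.0% to 65.2% of values per library were whole reads within 0.005 of a read, as estimated counts from a program that divides ambiguous reads would give. The recovered estimated reads, 50187279 to 56371476 per library over the listed genes, were used for depth and for an alternative test. The most abundant gene, Actb, took 1.22% to 1.51% of the signal. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 22.0 to 59.1 between pairs, so none was a copy of another library. Repeat libraries of 1 RNA sample would also differ by more than that noise, so this does not show that the samples were separate. Counting intervals cover counting error only.

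Genes with a mean of at least 1 CPM over the 8 libraries were tested on log2(CPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, genotype as the only term, two-sided, Benjamini-Hochberg). Positive log2 fold changes mean higher in CD103Tg. The pseudocount of 1 understates the change of low genes. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, leaving Itgae out of the lists. Means of marker lists were compared with an exact permutation test over 70 assignments, which cannot give a p below 0.0286. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used to recover reads, and matplotlib 3.10.9 for figures.

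The groups, tests, 36 gene lists, alternative settings and rule for named genes were fixed before the data were examined. The lists of sex chromosome genes and of identity and sort genes were given as values, and those of granulocyte and stromal markers had fewer than 3 tested members. The genes named are Itgae and the identity and sort genes, the 10 highest and 10 lowest called genes, the 4 members with the smallest p in each list with a called member (2 in other lists), and the sex chromosome genes. The highest and lowest genes needed a mean of at least 5 CPM in the higher group and no overlap between groups, and predicted models, pseudogenes and receptor variable segments were left out. Other genes, in the closing section and a few list members and markers in the results, were chosen after their values were seen. Some single genes that the rule selects are not reported here.

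Alternatives were pseudocounts of 0.1 and 5, no filter, a minimum mean of 5 CPM, median-of-ratios, quantile and equal-total scaling, robust eBayes, array weights, a minimum absolute log2 fold change of 1, the replicate number as a block, an estimated correlation, and leaving out each library in turn. Chosen after seeing the data were limma voom on the estimated reads, the Y-linked gene level as a covariate, and leaving out both libraries numbered 4. Voom called 3531 genes, 3514 of them shared with the reported calls. The median log2 fold change of all tested genes was -0.005.

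The fit was tested on simulated data for the CD103Tg against B6 comparison, at a dispersion of 0.02. Of 200 genes chosen for change, those that passed the filter were among the 11438 genes fitted, beside 11242 unchanged genes. It recovered 0% of genes changed 1.25-fold, 76% at 1.5-fold and 100% at 2-fold and 4-fold, and 9 of 143 calls were on unchanged genes. Camera gave p under 0.05 for 4.5% of 200 random lists. The simulation changed few genes and drew each on its own, whereas 31.2% of tested genes were called in the data. There the fit also called changes below 1.25-fold, such as Cd8a (1.18-fold, limma adjusted p = 0.00602). These rates are therefore not those of the data, and the random lists do not test camera where genes move together.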

Results

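RNA-seq was carried out on Ly6C+CXCR3+ CD8 T cells sorted from mouse lymph nodes, a surface phenotype that the submitters describe as memory phenotype. There were 2 groups, C57BL/6 (B6) mice and CD103Tg mice, which per the labels overexpress CD103, with 4 libraries each. CD103 is the integrin alpha E chain, encoded by Itgae, which pairs with the beta 7 chain (Itgb7) and binds E-cadherin (Cdh1). The table lists 13245 genes as TMM-scaled CPM. The estimated reads over these genes ranged from 50187279 to 56371476 per library, and 1 read was worth 0.0171 to 0.0203 CPM. Across genes, the correlation of log2 values was 0.989 to 0.992 between B6 libraries, 0.989 to 0.995 between CD103Tg libraries and 0.964 to 0.973 between the groups. The first principal component held 66.4% of the variance and separated the groups, and the second held 9.6%. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples.

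The comparison asked how the transcriptome of these cells differs between CD103Tg and B6 mice. Itgae, the gene of the transgene product (GRCm38 chromosome 11, 73090583 to 73147446), was at 76.1 ± 65.5 CPM in B6 and 4460 ± 861 CPM in CD103Tg (mean ± SD, n = 4 each). Its log2 fold change was 6.14 ± 0.39 (SE; limma adjusted p = 1.6e-06). The exact permutation test gave p = 0.0286, the smallest it allows with 70 assignments. The 4 B6 libraries stood at 41.4, 51.4, 37.5 and 173.9 CPM and the 4 CD103Tg libraries at 3468.7, 4692.5, 4168.7 and 5508.8 CPM. Cd247, which encodes the CD3 zeta signalling chain of the T cell receptor (chromosome 1, 165788681 to 165877277), also rose, from 345 ± 89.2 to 8710 ± 1000 CPM, a log2 fold change of 4.68 ± 0.15 (adjusted p = 3.03e-08). Its ratio to Itgae in the CD103Tg libraries was 2.40, 1.80, 2.44 and 1.43. The differences given below therefore cannot be assigned to CD103 apart from Cd247 or other features of the CD103Tg mice and libraries.

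Of the genes that define the sort and the cell type, Cxcr3 (520 ± 16.6 against 462 ± 34.3 CPM), Ly6c2 (2790 ± 321 against 3030 ± 229), Cd44 (155 ± 8.86 against 161 ± 17.2), Cd8b1 (1930 ± 139 against 1690 ± 134) and Cd3e (900 ± 62.7 against 830 ± 45.0 CPM) did not pass the test. Cxcr3 had an adjusted p = 0.0529 and passed under 3 other scalings, with adjusted p = 0.0264 to 0.0478. Cd8b1 passed as lower with quantile normalization (adjusted p = 0.002), with equal totals (0.0233), without B6 replicate 4 (0.0489) and without CD103Tg replicate 1 (0.0461), and Ly6c2 as higher with quantile normalization (0.0302). Itgb7, the partner chain, was at 1110 ± 63.8 and 1060 ± 9.34 CPM (adjusted p = 0.423). Cd8a fell by 0.24 ± 0.06 (SE) on the log2 scale. Il2rb, the beta chain of the interleukin-2 and interleukin-15 receptors, rose by 0.70 ± 0.08, Ly6a (Sca-1) by 2.94 ± 0.11 and Cdh1 by 2.90 ± 0.20, from 33.6 ± 9.89 to 257 ± 58.9 CPM.

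**Figure D1:**
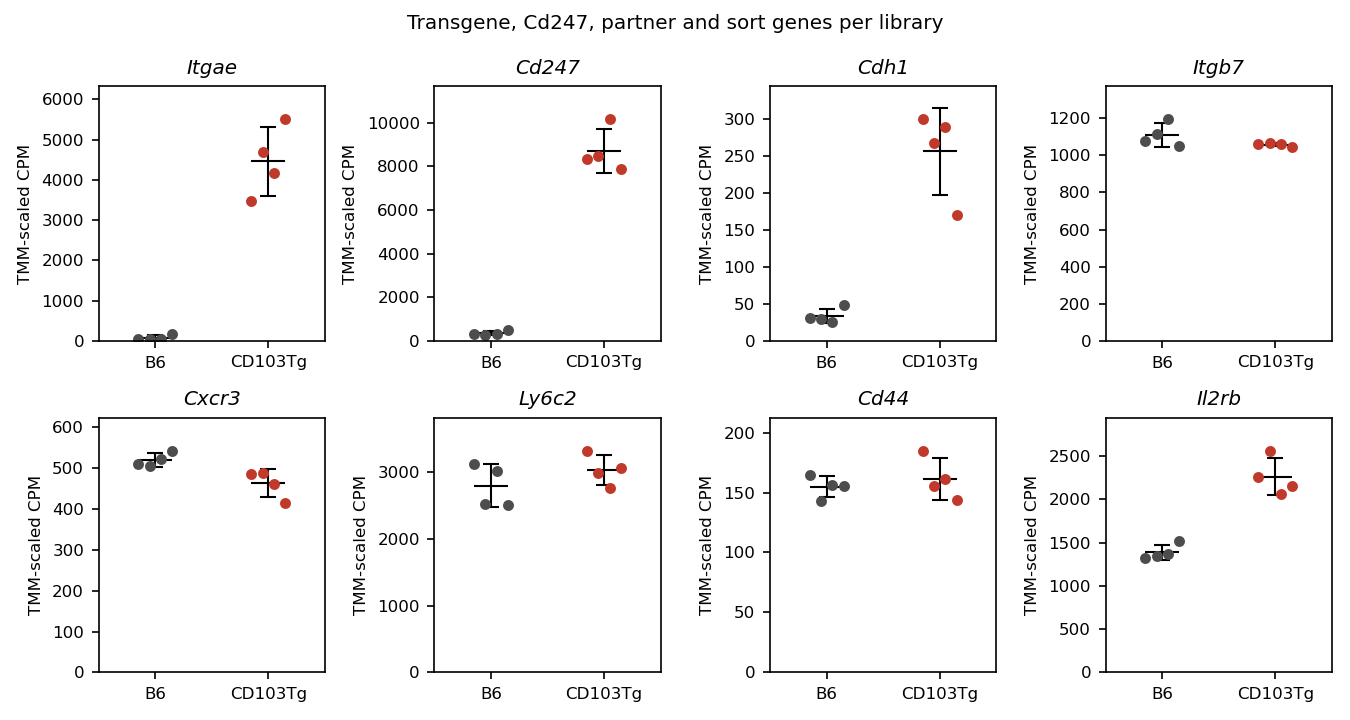
TMM-scaled CPM (linear axes from 0) of Itgae, Cd247, Cdh1, Itgb7 and 4 sort or memory genes in the 4 B6 and 4 CD103Tg libraries. Each point is a library in replicate order, the long line is the group mean and the bar 1 SD; Itgae lay between 37.5 and 173.9 CPM in B6 and between 3468.7 and 5508.8 CPM in CD103Tg.

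Over the whole table, 11503 genes were tested and 3592 differed at an adjusted p under 0.05 (limma-trend, Benjamini-Hochberg), 2000 higher and 1592 lower in CD103Tg. At least a 2-fold change on the log2(CPM + 1) scale was seen for 571 of them, 419 higher and 152 lower. All 4 libraries of a group lay above all 4 of the other in 3565 of the tested genes (31%), where chance gives 2.86%, and 3113 of these were among the called genes. The majority direction depended on the scaling: quantile normalization gave 1741 higher and 1995 lower, and rescaling to equal totals 1756 and 1848. Predicted gene models, pseudogenes and receptor variable segments made up 111 of the genes called higher and 194 of those called lower.

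Beside Itgae and Cd247, the largest increases were in Lgals3, the galectin-3 gene (log2 fold change 4.59 ± 0.32), Gzmb, encoding granzyme B (4.33 ± 0.28), the interferon-induced Ifi44 (4.01 ± 0.16), Cadps2 (3.93 ± 0.43), Fgl2 (3.78 ± 0.22), the sphingosine-1-phosphate receptor S1pr5 (3.68 ± 0.29), the immunoglobulin kappa constant gene Igkc (3.45 ± 0.66) and Fasl, the Fas ligand (3.41 ± 0.23). Gzmb went from 4.28 ± 2.51 to 101 ± 27.2 CPM and Fasl from 19.3 ± 6.91 to 213 ± 56.8 CPM. Cadps2 had 1 estimated read in the B6 libraries together against 3520 in CD103Tg, a CPM ratio of 3728 with a 95% counting interval of 669 to 147287. Igkc was uneven, at 5.77 to 85.18 CPM in CD103Tg against 0.22 to 2.32 CPM in B6, and lost its call with voom (adjusted p = 0.0607).

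The largest decreases were in the follicular homing receptor Cxcr5 (log2 fold change -3.07 ± 0.24), from 96.9 ± 5.73 to 11.6 ± 6.45 CPM, and in the sialyltransferase gene St6gal1 (-2.81 ± 0.30). Atp1b1 (-2.73 ± 0.28), Klra7 (-2.43 ± 0.26), Cnn3 (-2.34 ± 0.24), Id3 (-2.33 ± 0.26), App (-2.23 ± 0.20), Klra6 (-2.22 ± 0.20), Gabrr2 (-2.17 ± 0.20) and Ppic (-2.16 ± 0.21) followed. Klra6 and Klra7 encode Ly49 receptors and belong to a family of closely similar genes, so the division of reads among its members is uncertain. Id3, a transcriptional inhibitor kept high in naive and memory precursor cells, went from 143 ± 15.3 to 30.2 ± 15.4 CPM.

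**Figure D2:**
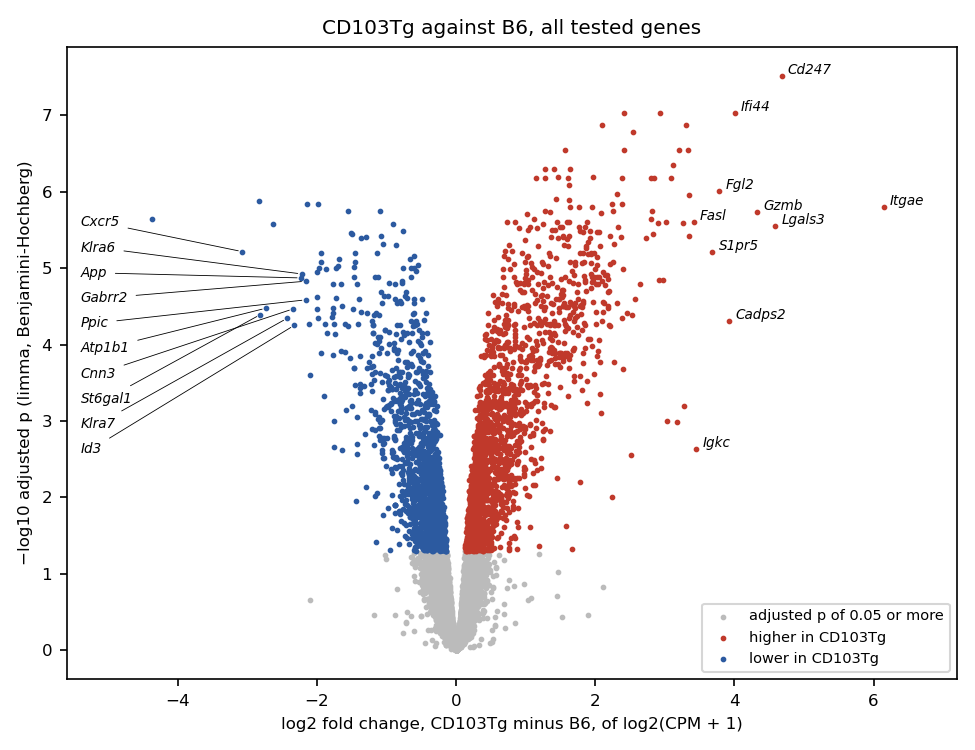
Log2 fold change (CD103Tg minus B6, of log2(CPM + 1)) against -log10 of the limma adjusted p for the 11503 tested genes. Red points are the 2000 genes higher and blue points the 1592 genes lower in CD103Tg at an adjusted p under 0.05; the named points are the 10 highest and 10 lowest genes under the rule for named genes.

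Of the gene lists fixed beforehand, 32 had at least 3 tested members. Camera with its preset correlation called 21 of them, 16 higher and 5 lower; with an estimated correlation it called 0, and another grouping of the 8 libraries also gave 21 calls. The one-way test of each list by fry, which does not compare a list with other genes, called 24. The list results are therefore given as counts of members, with the second camera value beside each list whose call it ended. Of all 11503 tested genes 31.2% were called, 2000 higher and 1592 lower, so counts near these shares say little about a list.

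Effector genes rose. Of 19 cytotoxic effector genes, 13 rose, 0 fell and 6 did not pass, and the same 13 and 0 were called adjusted over the list alone (camera adjusted p = 1.4e-06; adjusted p = 0.156 with an estimated correlation). Besides Gzmb and Fasl, the granule gene Nkg7 rose by 0.79 ± 0.08 and the granzyme B inhibitor Serpinb9 by 0.87 ± 0.08. Of 15 terminal effector differentiation genes, 14 rose and 1 did not pass, with 14 adjusted over the list alone (camera adjusted p = 1.7e-11; adjusted p = 0.115 with an estimated correlation). Id2, a transcriptional regulator of effector cells, rose from 73.3 ± 9.53 to 393 ± 85.0 CPM, and Bhlhe40 rose by 3.34 ± 0.20 and the lectin receptor gene Klre1 by 1.62 ± 0.09.

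Naive and stem-like genes fell: of 22, 16 fell, 1 rose and 5 did not pass, with 17 and 1 adjusted over the list alone (camera adjusted p = 7.33e-09; adjusted p = 0.115 with an estimated correlation). The transcription factor gene Lef1 went from 539 ± 25 to 252 ± 25.6 CPM, Tcf7 fell by 0.70 ± 0.07, the lymph node homing receptor Ccr7 by 0.66 ± 0.05 and the actinin gene Actn1 by 2.01 ± 0.20. Of 17 genes of memory phenotype CD8 T cells, 11 rose and 6 did not pass, with 12 rises and 2 falls adjusted over the list alone (camera adjusted p = 4.56e-06; adjusted p = 0.165 with an estimated correlation). Eomes, a T-box factor of memory cells, rose by 1.06 ± 0.08 and Itgb1 by 1.44 ± 0.10.

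Of 27 genes reported to be higher in tissue-resident cells, Itgae left out, 17 rose, 4 fell and 6 did not pass, with 18 and 4 adjusted over the list alone (camera adjusted p = 2.9e-05; adjusted p = 0.0798 with an estimated correlation). Ahr, the aryl hydrocarbon receptor, rose by 1.92 ± 0.14 and Cd101 by 1.02 ± 0.08, while the homing receptor Gpr15 fell by 1.94 ± 0.15. Of 19 genes lower in resident cells, 10 fell, 5 rose and 4 did not pass, with 10 and 6 adjusted over the list alone, and the list was not called (camera adjusted p = 0.264). Its median was -0.18, its mean 0.29 and its test direction down. Samhd1 (1.02 ± 0.07), Eomes and S1pr5 were among the 5 that rose.

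Interferon-stimulated genes rose: of 36, 34 rose and 2 did not pass, with 35 adjusted over the list alone and a median log2 fold change of 1.1 (camera adjusted p = 1.54e-23; adjusted p = 0.16 with an estimated correlation). Usp18, a negative regulator of interferon signalling, went from 77.8 ± 6.96 to 338 ± 39.9 CPM. The antiviral synthetase genes Oas1a and Oas3 rose by 2.55 ± 0.11 and 1.40 ± 0.07. All 32 cell cycle genes rose, and all 32 adjusted over the list alone, with a median of 1.84 (camera adjusted p = 2.4e-21; adjusted p = 0.16 with an estimated correlation). Top2a, a mitotic topoisomerase gene, went from 29.3 ± 6.35 to 122 ± 26.2 CPM, Rrm2 rose by 2.21 ± 0.16, Stmn1 by 1.82 ± 0.13 and Tpx2 by 1.86 ± 0.15.

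T cell receptor response genes fell more often than they rose: of 19, 11 fell, 3 rose and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.272 with an estimated correlation, and 0.0536 with the replicate number as a block). The early growth response genes Egr1 and Egr3 fell by 1.47 ± 0.13 and 1.16 ± 0.19 and Cd5, a surface marker of receptor signal strength, by 0.76 ± 0.06. The phosphatase gene Dusp5 rose by 0.68 ± 0.11. Of 24 genes of the receptor complex and its proximal signalling, 5 rose, 5 fell and 14 did not pass, also adjusted over the list alone (camera adjusted p = 0.875, with a mean of 0.17 and a test direction of down). After Cd247 its smallest p-values belonged to Malt1 (-0.47 ± 0.05), Themis (-0.32 ± 0.05) and Fyn (0.40 ± 0.06). Of 23 immediate early and heat shock genes, which respond to cell handling, 1 rose, 2 fell and 20 did not pass, with 0 and 2 adjusted over the list alone (camera adjusted p = 0.63). Zfp36 was at -0.66 ± 0.18, Ier5 at -0.27 ± 0.07 and Fosl2 at 0.40 ± 0.12, and Fosl2 lost its call without any one of B6 replicates 1 to 3 or CD103Tg replicates 2 to 4, and Ier5 without CD103Tg replicate 2 (adjusted p = 0.0519).

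Of 15 integrin genes other than Itgae, 6 rose, 3 fell and 6 did not pass, with 6 and 4 adjusted over the list alone (camera adjusted p = 0.233). Itga1 and Itgax, encoding alpha 1 and CD11c, rose by 2.31 ± 0.23 and 1.81 ± 0.19, and Itga6 fell by 0.71 ± 0.07. Of 38 integrin signalling and cytoskeleton genes, 16 rose, 4 fell and 18 did not pass, with 17 and 4 adjusted over the list alone (camera adjusted p = 0.00459; adjusted p = 0.357 with an estimated correlation). The calcium-binding genes S100a4 and S100a6 rose by 2.38 ± 0.13 and 3.26 ± 0.22 and Anxa2, the annexin A2 gene, by 1.64 ± 0.10. Of 19 TGF-beta signalling and response genes, 8 rose, 3 fell and 8 did not pass, with 8 and 6 adjusted over the list alone (camera adjusted p = 0.263). Smad3 rose by 0.67 ± 0.06 and Pmepa1 by 0.54 ± 0.07, Smad4 fell by 0.29 ± 0.05, and Cish, a suppressor of cytokine signalling, rose by 3.31 ± 0.14.

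Of 24 cytokine receptor genes, 12 rose, 5 fell and 7 did not pass, with 14 and 7 adjusted over the list alone (camera adjusted p = 0.0236; adjusted p = 0.239 with an estimated correlation). The interleukin-12 receptor genes Il12rb2 and Il12rb1 rose, the former by 3.12 ± 0.16 and the latter from 18.5 ± 2.16 to 45.2 ± 2.16 CPM, and Il10ra by 1.64 ± 0.09, while Il6st, the shared interleukin-6 receptor chain, fell by 1.51 ± 0.11. A minimum mean of 5 CPM ended that list's call (adjusted p = 0.07). Of 22 cytokine signalling genes, 9 rose, 2 fell and 11 did not pass, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.00987; adjusted p = 0.165 with an estimated correlation). With Cish, the suppressor genes Socs1 and Socs2 rose by 1.08 ± 0.10 and 2.65 ± 0.25 and the pro-apoptotic Bcl2l11 by 0.61 ± 0.06. Of 18 chemokine receptor and trafficking genes, 8 rose, 5 fell and 5 did not pass, with 8 and 6 adjusted over the list alone (camera adjusted p = 0.481, with a median of -0.04 and a mean of 0.42). Ccr2, a receptor for inflammatory chemokines, rose by 2.81 ± 0.15.

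Of 14 inhibitory receptor and exhaustion genes, 8 rose, 1 fell and 5 did not pass, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.115 with an estimated correlation). The members that rose included the ectoenzyme genes Entpd1 (2.73 ± 0.20), Cd38 (1.62 ± 0.11) and Nt5e (1.00 ± 0.09), which act on extracellular nucleotides. The receptor genes Cd160 (0.781 ± 0.107) and Tigit (0.986 ± 0.191) also rose. The member that fell was Tox (-0.345 ± 0.066, limma adjusted p = 0.00231). Pdcd1 (1.61 CPM in B6 and 1.93 in CD103Tg), Btla and Cd96 were among the 5 that did not pass. Of 20 natural killer receptor genes, 10 rose, 5 fell and 5 did not pass, also adjusted over the list alone (camera adjusted p = 0.0664). The list was called with quantile normalization (adjusted p = 0.0306), with equal totals (0.0348) and without CD103Tg replicate 2 (0.0391). Slamf7 rose by 1.17 ± 0.09, and Klra1 fell by 2.00 ± 0.18 along with Klra6. Of 6 genes of the Tc17 and type 3 programme, 5 rose and 1 did not pass, with 5 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.115 with an estimated correlation). The 4 with the smallest p-values were Ahr, Tmem176b (1.86 ± 0.14), Tmem176a (1.69 ± 0.15) and Batf (0.31 ± 0.07). Of 3 genes of the regulatory and type 2 programme, Gata3 rose by 0.39 ± 0.09, Ikzf2 fell by 1.59 ± 0.25 and Ctla4 was at -0.49 ± 0.18 (camera adjusted p = 0.481), with 1 rise and 2 falls adjusted over the list alone. Ctla4 (adjusted p = 0.0584) passed under several other settings, with adjusted p = 0.0124 to 0.0476.

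The 16 mitochondrially encoded genes tested were lower, 15 past the test and 16 adjusted over the list alone (camera adjusted p = 2.5e-10; adjusted p = 0.165 with an estimated correlation). mt-Co1 went from 4430 ± 506 to 2450 ± 204 CPM and mt-Cytb from 2220 ± 129 to 1310 ± 62.7 CPM. mt-Nd4 fell by 0.81 ± 0.08 and mt-Nd6 by 0.77 ± 0.09. Of 84 cytosolic ribosomal protein genes, 26 fell, 1 rose and 57 did not pass, with 31 and 1 adjusted over the list alone (camera adjusted p = 7.24e-08; adjusted p = 0.506 with an estimated correlation). Rpl22l1 fell by 0.72 ± 0.11, Rps27 by 0.62 ± 0.13 and Rps3a1 by 0.53 ± 0.13, and Rps27l rose by 0.49 ± 0.08. Of 30 nuclear oxidative phosphorylation genes, 6 rose and 24 did not pass, with 5 adjusted over the list alone (camera adjusted p = 0.0236; adjusted p = 0.631 with an estimated correlation). Atp5e rose by 0.41 ± 0.07, Ndufb8 by 0.31 ± 0.06, Atp5j by 0.25 ± 0.06 and Cox5a by 0.28 ± 0.07, and the list lost its call without B6 replicate 4 (adjusted p = 0.232), B6 replicate 2 (0.0584), CD103Tg replicate 1 (0.0971) or both libraries numbered 4 (0.215), and with array weights (0.063). Of 18 glycolysis genes, 6 rose, 1 fell and 11 did not pass, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.0867); Pfkp rose by 0.48 ± 0.07, Hk1 by 0.28 ± 0.04 and Slc16a1 by 0.36 ± 0.08, and Aldoa fell by 0.29 ± 0.06. Of 18 fatty acid and mitochondrial metabolism genes, 5 rose, 4 fell and 9 did not pass, with 6 and 4 adjusted over the list alone (camera adjusted p = 0.93). Srebf2, a regulator of sterol synthesis, fell by 0.58 ± 0.06, Lipa by 0.59 ± 0.07 and Pdk1 by 0.73 ± 0.11, and Scd2 rose by 0.79 ± 0.12.

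**Figure D3:**
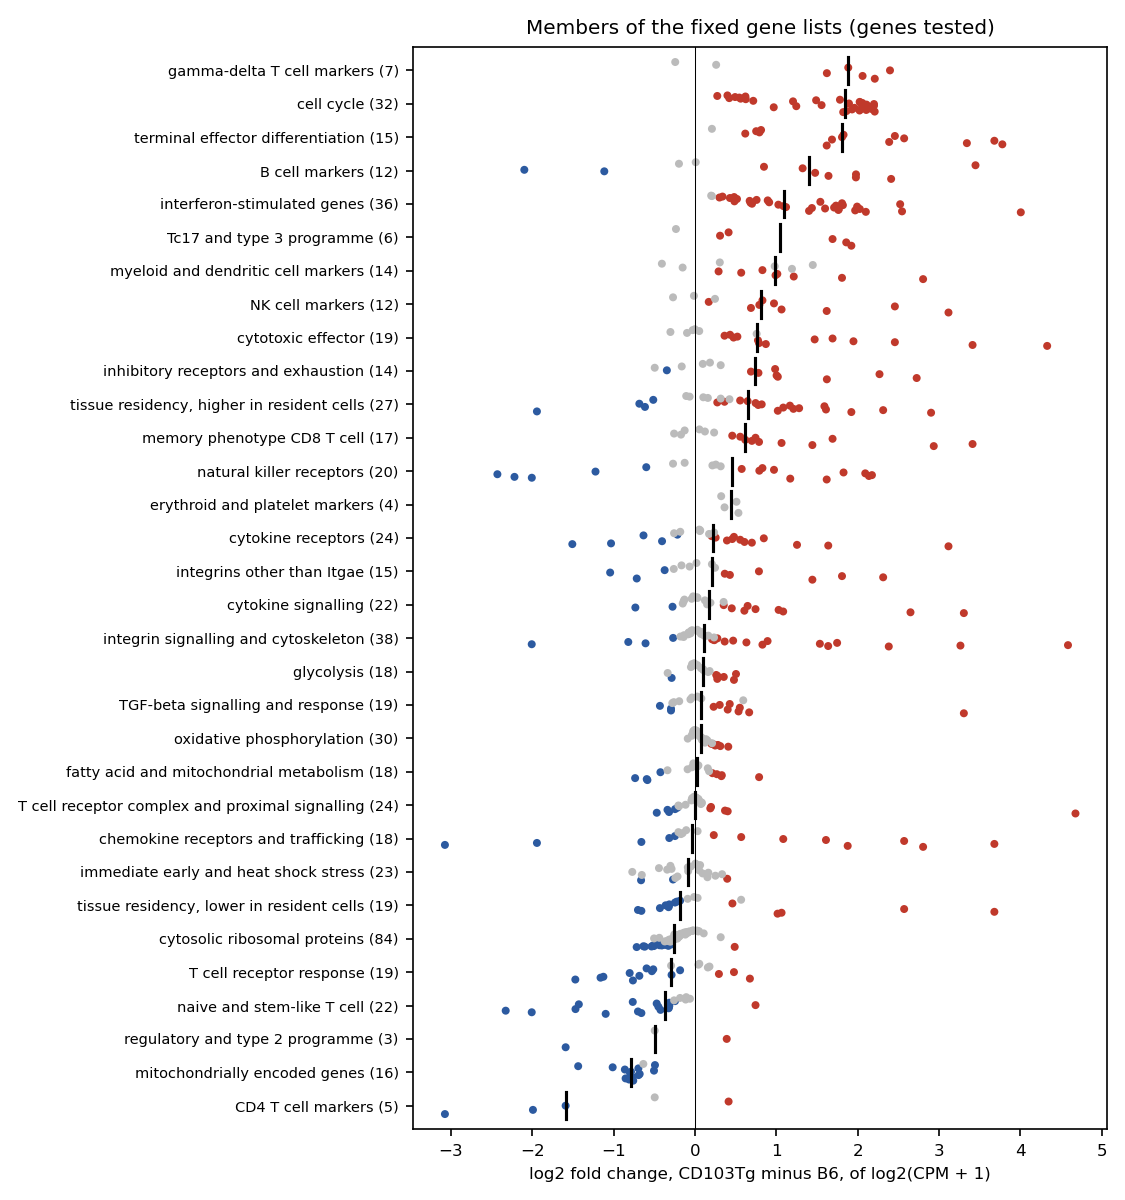
Log2 fold changes (CD103Tg minus B6, of log2(CPM + 1)) of the tested members of the 32 lists, with the number of members in brackets and a black bar at the median. Red and blue points passed an adjusted p under 0.05 as higher or lower and grey points did not; all 32 cell cycle genes and 34 of 36 interferon-stimulated genes lay on the higher side past the threshold.

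Markers of other cell types moved with the groups. The mean log2(CPM + 1) over the listed genes was higher in CD103Tg by 0.84 for B cells (18 genes), 0.82 for myeloid and dendritic cells (18 genes), 1.36 for gamma-delta T cells (8 genes) and 0.73 for natural killer cells (14 genes). It was lower by 0.94 for CD4 T cells (8 genes) and by 0.50 for stroma and endothelium (2 genes). The latter were Pecam1 (87.8 CPM in B6 and 63.3 in CD103Tg) and Epcam (6.6 and 4.21 CPM). Cd4 itself was not among the genes listed. Of the CD4 markers, Cd40lg (0.56 and 0.0487 CPM) and Zbtb7b (0.71 and 0.296 CPM) were very low, and Cxcr5 (96.9 and 11.6 CPM) fell most. Fewer CD4 or stromal cells and lower expression in the sorted cells cannot be told apart here. Each of these 6 differences had an exact permutation p = 0.0286 (two-sided; adjusted p = 0.0381 over 8 lists). The myeloid difference lost its call without any one of the B6 libraries (exact test, adjusted p = 0.0762). The difference itself was then still 0.74 to 0.91, and the test has fewer assignments with a library left out. Erythroid and granulocyte lists differed by 0.38 (exact p = 0.714) and 0.17 (exact p = 0.629). Of the natural killer list 12 of 14 genes, of the CD4 list 7 of 12 and of the myeloid list 4 of 20 also stood in a list other than those of cell types. Ccr2 and Itgax were among those of the myeloid list.

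Among B cell markers, 8 of 12 tested genes rose, 2 fell and 2 did not pass, also adjusted over the list alone (camera adjusted p = 0.00192; adjusted p = 0.115 with an estimated correlation). Cd22 rose from 15.5 ± 1.28 to 87.0 ± 10.9 CPM, and Cd74, H2-Aa and H2-Ab1, of the MHC class II pathway, rose by 1.98 ± 0.16, 1.64 ± 0.14 and 1.98 ± 0.18. The list's call was lost at a minimum mean of 5 CPM (adjusted p = 0.102). Of 14 myeloid and dendritic genes, 8 rose and 6 did not pass, with 9 adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.239 with an estimated correlation). Siglech rose by 1.22 ± 0.26 and Cd68 by 0.99 ± 0.21, both below 4 CPM. Of 7 gamma-delta genes, 5 rose and 2 did not pass, also adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.165 with an estimated correlation). Tcrg-C1, Tcrg-C2, Trgv2 and Tcrg-V4, all receptor gamma segments, rose by 2.21 ± 0.25, 2.40 ± 0.32, 2.06 ± 0.27 and 1.62 ± 0.22. The 2 that did not pass were the receptor delta gene Trdc (10.8 CPM in B6 and 13 in CD103Tg) and Cd163l1 (65.7 and 55.4 CPM). Of 12 natural killer markers, 9 rose and 3 did not pass, also adjusted over the list alone (camera adjusted p = 7.67e-06; adjusted p = 0.115 with an estimated correlation). They included Irf8, which rose by 0.69 ± 0.07. The 3 that did not pass were Itga2 (4.2 CPM in B6 and 5.19 in CD103Tg), Fcer1g (2.79 and 2.3 CPM) and Txk (356 and 351 CPM). Ncr1 (0.506 and 0.401 CPM) and Klra4 (1.68 and 0.0445 CPM) were too low on average to be tested, and neither was higher in CD103Tg. Of 5 CD4 markers, Cxcr5, Izumo1r (-1.99 ± 0.22) and Ikzf2 fell, Rora rose by 0.41 ± 0.11 (adjusted p = 0.0522 without CD103Tg replicate 1) and 1 did not pass, with 4 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0121; adjusted p = 0.21 with an estimated correlation). Of the 4 haemoglobin genes tested, 0 passed (camera adjusted p = 0.81), and Hba-a1 (log2 fold change 0.54 ± 0.95) and Hbb-bt (0.36 ± 0.66) varied within each group.

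The sex chromosome genes differed between libraries of the same group. B6 replicate 3 had 72.0 CPM of Xist and at most 0.02 CPM of Ddx3y, Eif2s3y, Kdm5d and Uty. B6 replicates 1, 2 and 4 had 114.05 to 138.92 CPM of Ddx3y, and in turn 0.02, 0.04 and 1.71 CPM of Xist. CD103Tg replicate 2 had 113.01 CPM of Ddx3y and 0.02 CPM of Xist. CD103Tg replicates 1, 3 and 4 had both Xist, at 21.71, 36.42 and 45.2 CPM, and Ddx3y, at 48.47, 29.39 and 20.79 CPM. Having both, CD103Tg replicates 1, 3 and 4 held female and male RNA, which argues against 1 mouse as the source of each. A pool of mice and a mixing of samples cannot be told apart. The sex make-up of the libraries thus differed between the groups. Whether a library was made from 1 mouse or from a pool is not given in the sources used here, so what the 4 replicates and their SDs stand for is open. None of these 5 genes passed the test with all 8 libraries. Without B6 replicate 3, Ddx3y, Eif2s3y, Kdm5d and Uty were lower in CD103Tg, with adjusted p = 0.0306, 0.0378, 0.042 and 0.0488. With the level of the Y-linked genes as a covariate, chosen after seeing the data, 3441 genes were called, 3366 of them shared with the reported 3592. Leaving out both libraries numbered 4, which carried the most haemoglobin RNA of their groups, 3657 genes and 20 lists were called.

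**Figure D4:**
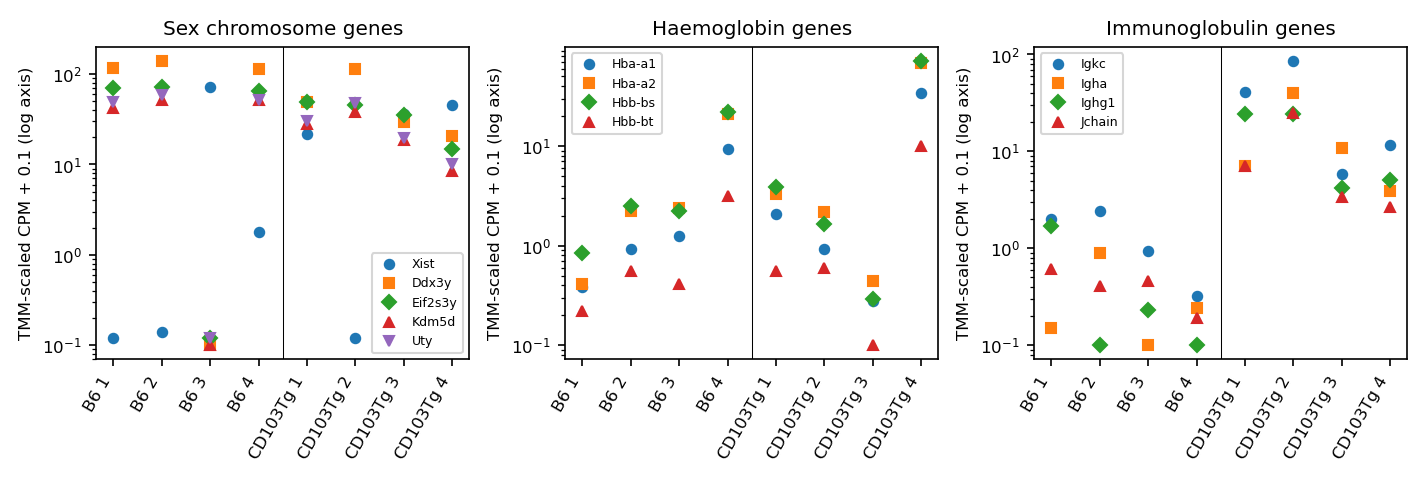
TMM-scaled CPM plus 0.1, on log axes, of sex chromosome, haemoglobin and immunoglobulin genes in each of the 8 libraries, 1 point per gene and library. Xist and Y-linked genes were both present in CD103Tg replicates 1, 3 and 4, haemoglobin was highest in the libraries numbered 4 of both groups, and Igkc ranged from 5.77 to 85.18 CPM in CD103Tg.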

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

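The carry-over, neighbourhood and receptor complex tests in this part were chosen only after the result was seen, and the shared-sequence test before. Of 268 sets of 4 libraries examined (each named gene in each group, on the CPM scale), 18 (6.7%) held a library far from the others of its group, where chance gives about 1 in 20. Of these, 10 were in a library numbered 4, 6 in B6 and 4 in CD103Tg.

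B6 replicate 4 stood above the other B6 libraries for the gene of the transgene product and for Cd247. Itgae was at 173.85 CPM against 37.47 to 51.44, and Cd247 at 477.85 against 285.42 to 314.81. Carry-over of CD103Tg material may account for this, at a share of 2.95% of the CD103Tg mean for Itgae and 2.1% for Cd247. Genes at least 10 times higher in CD103Tg had a median excess of 2.08% in that library (95% bootstrap interval -0.64 to 3.83, 31 genes), but the outcome turned on the selection, which was made after values had been seen: 2.82% (1.17 to 4.65, 83 genes) at 5 times and -0.64% (-2.7 to 1.78, 15 genes) at 20 times. With each CD103Tg library in turn as the source, the 10-times median was 1.61% to 4.76%. Gzmb (-2.7%), Lgals3 (-0.64%) and Cadps2 (0.1%) lay below 2%, so carry-over and a library of its own character cannot be told apart, since the genes span both sides of the share that is needed. The share of Gzmb is uncertain, since B6 replicates 1 to 3 spanned 3.09 to 7.94 CPM. Those of Lgals3 and Cadps2 depend on the source. CD103Tg replicate 4 had 22.21 and 3.77 CPM of them, against 53.39 to 85.08 and 17.48 to 24.46 in the other CD103Tg libraries. B6 replicate 4 also held 1.71 CPM of Xist, against 0.02 and 0.04 in B6 replicates 1 and 2, which like it had Y-linked RNA. Xist was present in CD103Tg replicates 1, 3 and 4 but also in B6 replicate 3 (72 CPM), so this does not name a source. A mixed or mislabelled part of the sample and a biological difference between mice were not tested. Without B6 replicate 4, 3459 genes were called, 3120 of them shared with the reported calls.

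Cd247 was higher in CD103Tg alongside Itgae, by 4.68 on the log2 scale against 6.14, but within CD103Tg the library with the most Itgae had the least Cd247. The annotated transcripts of both genes share 0 words of 25 bases, which argues against reads shared between them. The other tested genes within 500 kb of Cd247 had a median log2 fold change of -0.08 (5 genes), which argues against raised transcription of its whole neighbourhood, and the other receptor complex genes one of -0.2 (6 genes), which argues against a rise of the whole complex. A hypothesis left open is that the transgenic cells carry extra Cd247 sequence, for example in the construct or the strain, which the deposited gene-level values could not test. Elements of the construct are not given in the sources used here.

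Other libraries far from the rest of their group are given as values. In B6 replicate 4, Cadps2 was at 0.02 CPM against 0 in the other B6 libraries, Socs2 at 1.93 against 0.27 to 0.52, Hba-a1 at 9.29 against 0.28 to 1.14 and Hbb-bt at 3.05 against 0.12 to 0.45. In CD103Tg replicate 4, Hba-a1 was at 34.26 against 0.18 to 1.98, Hbb-bt at 9.87 against 0 to 0.49, Klra6 at 2.64 against 1.09 to 1.34 and Gpr15 at 6.25 against 3.94 to 4.31. In B6 replicate 3, Xist was at 72 against 0.02 to 1.71 and Eif2s3y at 0.02 against 64.36 to 72.13. In B6 replicate 2, Samhd1 was at 173.42 against 206.21 to 212.67 and Scd2 at 119.83 against 82.03 to 86.69. In CD103Tg replicate 1, Itgax was at 33.38 against 21.99 to 22.65, Tmem176b at 10.49 against 7.74 to 7.95, Itga6 at 61.71 against 72.73 to 74.77 and Fosl2 at 8.56 against 10.55 to 10.68.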

How the results depend on the processing

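Voom, the Y-linked covariate and leaving out both libraries numbered 4 were chosen only after the result was seen. The count of called genes stayed between 2978 and 3968 under the planned scalings, filters, pseudocounts and weights, and between 2771 and 3583 without each library in turn. A minimum absolute log2 fold change of 1 gave 571 genes (419 higher, 152 lower), by its construction. Camera called 18 to 22 lists under these settings, but 0 with an estimated correlation, which ended all 21 calls. Itgae kept its call under every setting, with log2 fold changes of 5.91 to 6.64 without each library in turn. Igkc lost its call with voom (adjusted p = 0.0607), though its log2 fold change there was 4.505 against 3.449 as reported. Whether the replicate numbers pair the samples is open: same-numbered deviations correlated at 0.22, 0.35, -0.08 and 0.12, and B6 replicates 1 and 2 correlated best with their own number while 3 and 4 did not. With the replicate block 3682 genes were called, 3389 of them shared with the reported calls, and the T cell receptor response list lost its call (adjusted p = 0.0536).

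Directions turned only for genes and lists that were not called with all 8 libraries, and the cause was not tested. At a pseudocount of 5, Kdm5d was at -0.18, Uty at -0.14 and Ddx3y at -0.22. Without B6 replicate 3, the library lacking Y-linked RNA, these were at -1.20, -1.17 and -1.49 and Eif2s3y at -1.04. Without CD103Tg replicate 2 they were at -0.08, -0.07 and -0.21, and with the Y-linked level as a covariate at -0.068, -0.018 and -0.092; without B6 replicate 2, where they did not turn, they were at 0.708, 0.791 and 0.883, and Eif2s3y at 1.012. Over the libraries left out, Cd44 ranged from -0.012 to 0.107 and Hba-a1 from -0.527 to 1.182, and Hbb-bt was at -0.423 with voom. Lists that turned had these camera adjusted p-values there. For chemokine receptors it was 0.702 and for fatty acid metabolism 0.938 at a minimum mean of 5 CPM. For fatty acid metabolism it was 0.977 without B6 replicate 2 and 0.946 without CD103Tg replicate 4, for the receptor complex 0.851 without CD103Tg replicate 4 and 0.91 without both libraries numbered 4, and for immediate early genes 0.783 without B6 replicate 4. For erythroid markers it was 0.999 with array weights, 0.961 without B6 replicate 1, 0.472 without CD103Tg replicate 4 and 0.995 with voom. Over all libraries left out in turn, whether the direction turned or not, the values ranged from 0.801 to 0.977 for fatty acid metabolism, 0.69 to 0.977 for the receptor complex, 0.145 to 0.978 for immediate early genes and 0.429 to 0.961 for erythroid markers. Differences in marker means ranged from -0.11 to 0.4 for granulocytes and from -0.54 to 0.94 for erythroid cells.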

Other observations

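The B cell, fry and separate-locus tests in this part, and the 5 lists of the next sentences, were chosen only after the result was seen. Of 19 genes of MHC class I antigen processing, 13 rose and 6 did not pass (camera adjusted p = 2.1e-05 over the 5 lists; adjusted p = 0.34 with an estimated correlation, as for each of these lists). H2-Q6 rose by 0.75 and the peptide transporter gene Tap1 by 0.42, while B2m was at 0.03. Of 15 interferon-inducible GTPase genes, 11 rose, 1 fell and 3 did not pass (camera adjusted p = 2.1e-05), with Iigp1 going from 14.2 to 76.1 CPM and Tgtp1 lower by 0.35 on the log2 scale. Of 17 endoplasmic reticulum folding genes, 9 rose and 8 did not pass (camera adjusted p = 0.000447), among them Sdf2l1 (0.77), Pdia3 (0.47) and the chaperone gene Hspa5 (0.56).

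Of 19 cholesterol synthesis genes, 6 fell, 1 rose and 12 did not pass (camera adjusted p = 0.0267). Sqle fell by 0.82 and Hsd17b7 by 0.59, and Sc5d rose by 0.50. Of 6 T cell receptor constant and CD3 genes, Trac, Trbc1 and Trbc2 fell by 0.65, 0.32 and 0.29 and the 3 CD3 genes did not pass (camera adjusted p = 0.0267).

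Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many called genes, with 3592 against at most 2 in any other. The other splits mix the groups, so that a group difference adds to their spread and lowers their calls. The smallest share this count can give is 1 in 35, so it does not exclude chance. For lists called by camera at its preset correlation, 2 of the 35 splits gave as many. The real one had 21 and the highest other also 21, and the other splits had a median of 5.5. That other split set B6 replicates 1, 3 and 4 with CD103Tg replicate 4 against the rest and called 0 genes. Counted for fry only after that result was seen, 1 of the 35 splits, the real one, gave as many lists, 24 against at most 0 in any other. The fry count has the same limits as the count of genes.

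Some immunoglobulin transcripts were higher in CD103Tg: Igkc, Jchain (2.57 to 25.09 against 0.09 to 0.51 CPM) and Igha (3.83 to 40.3 against 0 to 0.8 CPM). Ighg2b, at 0.04 to 43.95 against 0.04 to 1.51 CPM, did not pass (limma adjusted p = 0.147). Ighm fell from 763.1 to 851.71 CPM in B6 to 303.77 to 493.35 CPM. B cells in the sort, which the CD8 gate would remove, are argued against by the other B cell genes, whose median log2 fold change was -0.2 (7 genes). RNA of antibody-secreting cells remains a candidate source, though the CD8 gate would remove such cells too. Of 4 genes listed for them, 3 (Mzb1, Txndc5 and Xbp1) had all CD103Tg libraries above all B6 libraries. Txndc5 and Xbp1 were already at 195.65 to 224.07 and 58.75 to 76.19 CPM in B6, so only Mzb1 (0.15 to 1.8 against 0 to 0.12 CPM) was low there. Expression by the sorted cells themselves was not tested.

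It was asked whether genes strongly lower in CD103Tg lie near each other in the genome, as a flanking chromosome segment from another strain or a local rearrangement may cause. Among 19 genes with a log2 fold change below -2, 3 pairs not of 1 gene family lay within 1 Mb, above the 95th percentile of 1 pair in 10000 random sets. All 3 pairs, however, come from 1 stretch of chromosome 16 (23175280 to 23360350), where B630019A10Rik, BC106179 and St6gal1 overlap or adjoin, so that shared reads or transcription are possible. With genes starting within 100 kb merged, a rule set after that was seen, 0 pairs remained, and since random sets have a median of 0 this cannot be told apart from no clustering.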
